A study of Mus musculus with 6 samples.

How the data were processed

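Bone marrow-derived macrophages from 3 mice were treated with 2 µM thiothixene or DMSO for 24 h on day 6, and 6 total RNA libraries were read as paired ends on an Illumina instrument, per the labels' protocols. The mouse letter in each title and the treatment label placed each library in its group. The authors deposited whole-number counts per gene, not normalized, a table per library with 56691 gene rows and 5 rows that name no gene. FastQC 0.11.8, Trim Galore 0.6.10, STAR 2.7.11b, DESeq2 1.44 and the mm10 build are named, without their roles, per the submitters' processing notes. The counting program, its strand setting and the annotation release are not given in the sources used here. Reads outside any gene made up 43.07% to 44.35% of all rows' counts per library, and reads not aligned 1.85% to 4.978%. These rows stayed out of library sizes and tests.

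Gene symbols, GC content, lengths and the GRCm38 positions came from a GENCODE annotation of that build. Without version numbers 52073 identifiers matched and 4618 did not, and the latter held 0.4% of gene counts. With version numbers 35 matched, so the deposited tables rest on another annotation release. Antisense and overlapping genes were not singled out as findings, since the counting is not stated to use strand.

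The main test was edgeR 4.0.16 (R 4.3.3), quasi-likelihood with robust fitting, TMM scaling and its expression filter, treatment as the sole term and Benjamini-Hochberg adjustment at 0.05. That left 14856 genes. Standard errors are the absolute log2 fold change divided by the square root of F, and 95% intervals use the fit's degrees of freedom. Gene lists, 26 in all, were fixed before the data were examined, as were the tests, the first set of alternatives and the rule for named genes. Lists with at least 3 tested members, 24 of them, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), again with an estimated correlation, and with fry. A list's median and mean are over its members' limma coefficients, a scale chosen after the values were seen so that they match the test. Members above or below 0 are counted from edgeR.

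The rule named Arg1, Stra6l and Drd1 to Drd5, the genes of largest change and of smallest p among called genes, and up to 4 called members of each list or, with none called, the 2 of highest mean CPM. As no gene was called, the middle parts were empty. A gene that the rule names is not reported here. The 10 genes of smallest p in each direction were added after their values were seen.

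The libraries share mice across treatments, by the letter in the titles, so the letters pair them. Deviations from the group means correlated at -0.131 for mouse a, 0.318 for mouse b and -0.301 for mouse c, and the highest correlation, 0.486, was between the thiothixene library of mouse a and the DMSO library of mouse c. The common dispersion was 0.236 with the block and 0.212 without it. With the mouse as a replicate block 0 genes passed, as without it.

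Alternatives fixed before the data were examined were the block, RLE size factors, no filter, a filter of CPM at least 1 in 3 libraries, DESeq2 1.42.0, limma-voom, other thresholds and leaving out libraries or mice. Chosen after the data were seen were per-library offsets for GC content and length (splines with 5 degrees of freedom), library quality weights, DESeq2 with the block, and fits without libraries that stand apart. These last fits keep a lone DMSO library, from mouse a, which is assumed to vary like the thiothixene libraries.

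The procedure was tested on simulated data for 14856 genes with the spread of these libraries. Of 50 genes planted at each size, edgeR recovered 0 at a log2 fold of 1, 14 at 2, 35 at 3 and 40 at 4. Among its 94 calls, 5 were genes planted without a change. Each simulated gene was drawn independently, whereas the real libraries deviated together over many genes. These rates therefore do not carry over directly to the real data. The replicates are separate mice per the labels. Limits from counts of 0 (3 counts) cover counting error only, and the 95% intervals of fold changes include the spread between libraries.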

Results

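Gene expression was measured by RNA sequencing in mouse bone marrow-derived macrophages, primary phagocytes grown from marrow precursors. Cells from 3 mice, named a, b and c, were treated on day 6 of culture with 2 µM thiothixene or with the solvent DMSO for 24 h. Thiothixene is an antipsychotic drug that blocks dopamine receptors. Each mouse gave a library per treatment, so 3 thiothixene libraries stood against 3 DMSO libraries. Counts assigned to genes were 20264090, 18548095 and 20091492 in the thiothixene libraries of mice a, b and c. The DMSO libraries held 21327185, 10472349 and 22297520 counts.

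The series title names dopamine antagonism, vitamin A-dependent induction of Arg1 and continued efferocytosis, the uptake of dead cells. The comparison asked which transcripts differed after drug treatment. Stra6l, which encodes a retinol-binding protein receptor related to STRA6 (identifier ENSMUSG00000028327.15, chromosome 4, 45848664 to 45887008 on the plus strand of GRCm38), ranked first of 14856 tested genes by p. Its level was 35.6 ± 0.766 CPM (counts scaled to library size; SD, n = 3) with thiothixene and 6.91 ± 1.81 CPM with DMSO. The log2 fold change was 2.35 (SE 0.33), a 5.12-fold difference, and thiothixene was the higher library in 3 of 3 mice. Its unadjusted p in edgeR's quasi-likelihood test was 7.71e-05. Adjusted over all tested genes, Stra6l did not pass in that test, where the smallest adjusted p was 0.9998. It passed when adjusted over the list alone, as the only called member among 12 tested genes of vitamin A uptake and retinoid metabolism. That list was drawn up with the series title in hand, so this call is not independent evidence. DESeq2 called Stra6l with an adjusted p of 7.09e-06, and edgeR without a low-count filter gave an adjusted p of 0.037.

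Arg1, the arginase of alternatively activated macrophages (ENSMUSG00000019987.10, chromosome 10, 24915221 to 24927484 on the minus strand of GRCm38), was close to the limit of detection. The thiothixene libraries held 14, 8 and 10 counts and the DMSO libraries 14, 9 and 22 counts for mice a, b and c. Means were 0.529 ± 0.122 CPM with thiothixene and 0.856 ± 0.203 CPM with DMSO (SD, n = 3). The log2 fold change was -0.68 (SE 0.75), with a 95% interval from -2.39 to 1.04, and edgeR's adjusted p was 1. The interval leaves a rise of up to that upper bound open. Transcripts of the dopamine receptor genes Drd1, Drd3 and Drd5 had 0 counts in all 6 libraries. A count of 0 allows a level of up to 0.128 CPM in the DMSO library of mouse c and up to 0.335 CPM in that of mouse b, for counting error only. Drd2 had 10 counts in the thiothixene library of mouse a, 1 count in the DMSO library of mouse b and 0 in the rest. Drd4 had 1 count, in the DMSO library of mouse b. None of these receptors was abundant enough to be tested.

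**Figure D1:**
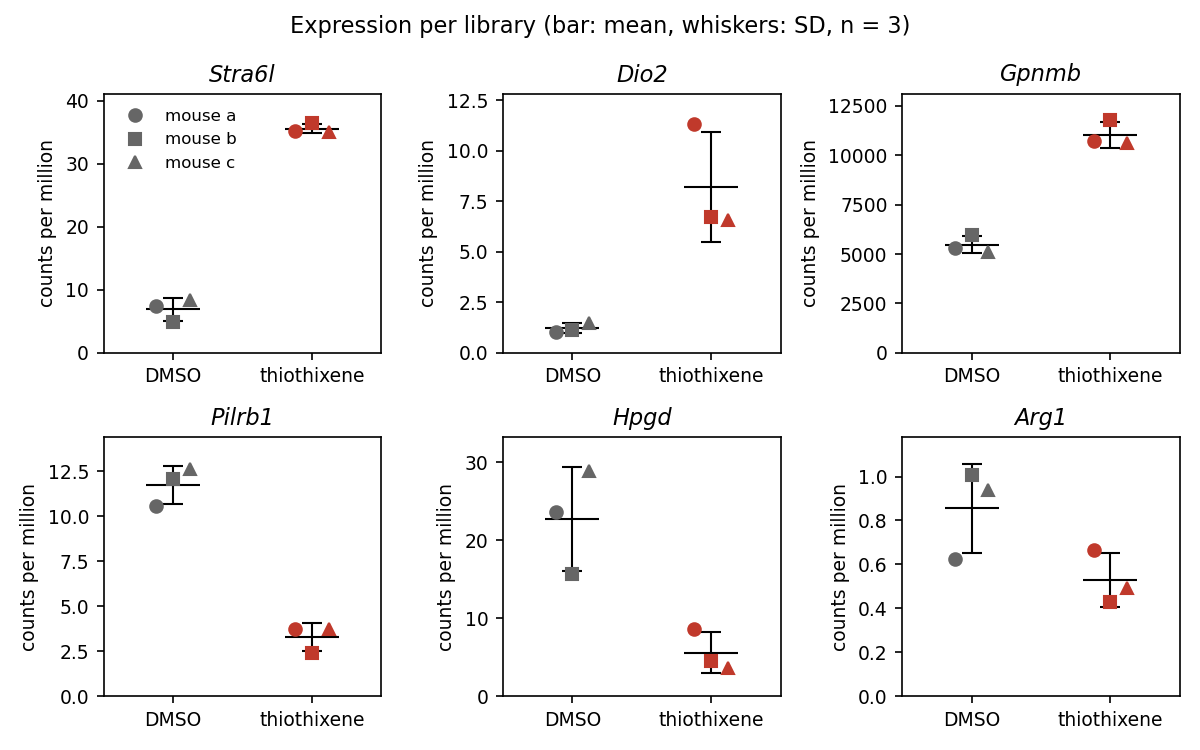
Level in CPM of 6 genes in each library, with DMSO in grey and thiothixene in red, symbols for mice a, b and c, a bar at the mean and whiskers of 1 SD (n = 3 per group). Stra6l, Dio2 and Gpnmb were higher and Pilrb1 and Hpgd lower in all 3 thiothixene libraries than in all 3 DMSO libraries, while Arg1 overlapped; Stra6l, Arg1 and Gpnmb fall under the rule fixed before the data were examined, and the other 3 genes were chosen after their values were seen.

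Over all genes, 0 passed an adjusted p of 0.05 in edgeR. At an unadjusted p under 0.05 there were 256 genes, 131 higher and 125 lower with thiothixene, against 743 expected by chance. DESeq2 called 2 genes, Stra6l and Dio2 (adjusted p 0.00173), and limma-voom called 0. Levels of 576 genes were higher and of 412 genes lower in all 3 thiothixene libraries than in all 3 DMSO libraries. Together these were 6.65% of tested genes, where chance gives 10% if the pairing by mouse is ignored. Libraries of the same treatment lay far apart. The correlation of log2 CPM across genes, which are not independent replicates, was 0.825 between the DMSO libraries of mice b and c and 0.981 between the thiothixene libraries of mice b and c. The biological coefficient of variation was 46%. Limma-voom with library quality weights, a setting chosen after the data were seen, called 25 genes, 9 higher and 16 lower. Its weights were 6.227 and 2.746 for the thiothixene libraries of mice b and c and 2.283 for the DMSO library of mouse a. They were 0.537 for the thiothixene library of mouse a and 0.209 and 0.228 for the DMSO libraries of mice b and c. It thus rested mainly on thiothixene from mice b and c against DMSO from mouse a, so treatment and mouse were poorly separated. Leaving out the thiothixene library of mouse a and the DMSO libraries of mice b and c, also chosen afterwards, gave 1105 calls, 636 higher and 469 lower. That fit compared 2 thiothixene libraries with a lone DMSO library from another mouse, so treatment and mouse were not separated, and the lone library was assumed to vary like the others.

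**Figure D2:**
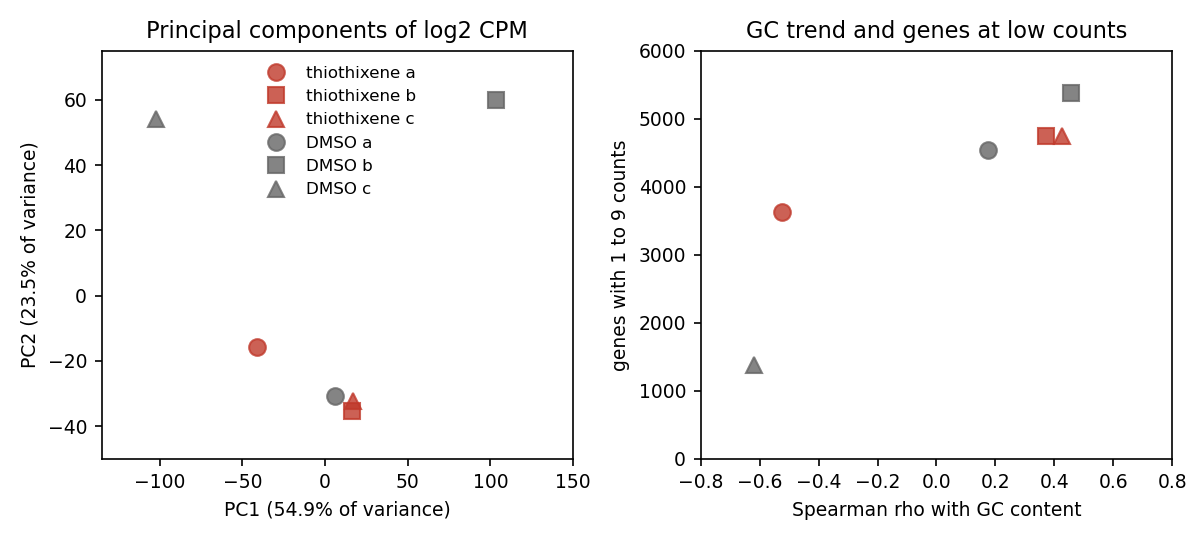
Left, position of the 6 libraries on the first and second principal components of log2 CPM (54.9% and 23.5% of variance); right, number of genes with 1 to 9 counts against the correlation, across genes, of each library's deviation with GC content. The DMSO libraries of mice b and c lay at opposite ends of the first component, and the DMSO library of mouse c had 1381 genes at such counts where that of mouse b had 5383.

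With no gene past the threshold, the genes of smallest p were picked after their values were seen and are given as levels. On the higher side Dio2, a deiodinase that activates thyroid hormone, measured 8.21 ± 2.72 CPM with thiothixene and 1.21 ± 0.247 CPM with DMSO (log2 fold change 2.75, SE 0.47). Mmp12, macrophage elastase, measured 1266 ± 240 against 467 ± 141 CPM, a 2.71-fold difference. Gpnmb, a lysosomal glycoprotein, measured 11036 ± 654 against 5465 ± 434 CPM (1.01, SE 0.25). The log2 fold changes of the other leading genes were 1.49 for Rps6ka2, 1.23 for Bhlhe40, 2.43 for Cd200, 1.46 for Chst11 and 1.66 for the cystine transporter gene Slc7a11. On the lower side the prostaglandin-degrading enzyme gene Hpgd measured 5.59 ± 2.64 against 22.7 ± 6.67 CPM (-2.02, SE 0.45). Log2 fold changes were -1.83 for Pilrb1, -1.19 for Clec4a1, -2.40 for Adgre4, -1.47 for Tmem176b, -1.11 for the coagulation factor XIII gene F13a1, -0.99 for Hgsnat, -1.36 for Rhobtb1 and -1.13 for Tlr2. Pilra measured 19.2 ± 2.91 against 52.3 ± 18.5 CPM. Pilrb1, Pilra and Clec4a1 have close paralogs. Sharing of reads with these was not measured, and their levels are given as uncertain. Of these 20 leading genes, Stra6l and Atp6v0d2 included, 15 were called by limma-voom with library quality weights. The genes were ranked on these same libraries, so this is not a separate check.

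Of 25 tested cholesterol synthesis and SREBP2 target genes, 21 had a log2 fold change above 0, with a median of 0.45, and the list's median deviation was higher in all 3 thiothixene libraries than in all 3 DMSO libraries. Camera, which tests a list against all other genes, gave an adjusted p of 1.32e-05 with its preset correlation. With an estimated correlation, here -0.037 against the preset 0.01, camera's adjusted p was 0.134. Fry gave an adjusted p of 0.0404. In fits that left out a single library, camera's adjusted p at the preset correlation was 0.00893 or lower. The abundant members Srebf2 and Fdft1 had log2 fold changes of 0.40 (SE 0.33) and 0.00 (SE 0.31). Of 15 fatty acid synthesis and SREBP1 target genes 11 were above 0, with a median of 0.46 (camera adjusted p 0.00363, and adjusted p 0.313 with an estimated correlation). Acly measured 236 ± 25.3 against 175 ± 43.8 CPM and Fasn, fatty acid synthase, 172 ± 40.4 against 99.3 ± 28.8 CPM. Among 12 tested LXR target genes the adjusted p was 0.613, with Apoe at -0.69 (SE 0.74) and Lpl at -0.12 (SE 0.29).

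Lysosome and TFEB target genes were above 0 for 38 of 57 members, with a median of 0.19 (camera adjusted p 0.00309, and adjusted p 0.547 with an estimated correlation). Without the DMSO library of mouse a the adjusted p was 0.108, and without that of mouse c it was 0.335. Gpnmb was among them, as was cathepsin B (Ctsb) at 13551 ± 250 against 12325 ± 4193 CPM. Osteoclast markers had 5 of 7 members above 0 and a median of 0.52 (adjusted p 0.0101, and adjusted p 0.313 with an estimated correlation of -0.0599). Camera's adjusted p was 0.114 without the DMSO library of mouse a, 0.059 without that of mouse b and 0.106 without the thiothixene library of mouse c, and 0.154 without a low-count filter. Atp6v0d2, a proton pump subunit, measured 123 ± 37.6 against 53.0 ± 5.53 CPM. It passed when adjusted over the list alone, as 1 called member, but with the mouse as a block 0 members passed. Nfatc1 had a log2 fold change of 0.25 (SE 0.33). Glycolysis and hypoxia genes were above 0 for 17 of 24 members, median 0.20 (adjusted p 0.00639, and adjusted p 0.547 with an estimated correlation), although the abundant Pkm and Gapdh were at -0.14 (SE 0.41) and -0.35 (SE 0.53). Without the DMSO library of mouse a its adjusted p was 0.205, and without the thiothixene library of mouse c 0.107.

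Type I interferon response genes were below 0 for 24 of 25 members, with a median of -0.51 (camera adjusted p 1.44e-07, and adjusted p 0.547 with an estimated correlation of 0.441). The groups overlapped, since the list's median deviation was 0.26 in the thiothixene library of mouse c and -0.004 in the DMSO library of mouse b. Within each mouse the thiothixene library was the lower. Deviations were -0.17 against 0.20 for mouse a, -0.70 against -0.004 for mouse b and 0.26 against 0.58 for mouse c. With the mouse as a block, camera's adjusted p at the preset correlation was 1.48e-08. Bst2 and Ifi204 had log2 fold changes of -0.56 (SE 0.65) and -0.56 (SE 0.35). Cell cycle genes were below 0 for 31 of 35 members, median -0.12 (adjusted p 0.0089, and adjusted p 0.547 with an estimated correlation), with Pcna at -0.07 (SE 0.28) and Mki67 at -0.04 (SE 0.36). The cell cycle adjusted p was 0.108 without the DMSO library of mouse a, 0.134 without that of mouse b and 0.392 without the thiothixene library of mouse c. All 15 antigen presentation genes were below 0, median -0.24 (adjusted p 0.0483, and adjusted p 0.776 with an estimated correlation). The call was lost with the mouse as a block (adjusted p 0.0588), without a low-count filter (0.0987), and without the DMSO library of mouse a (0.139) or the thiothixene library of mouse a (0.58) or b (0.0623). Without the DMSO library of mouse b the adjusted p was 0.681 and the direction turned, with a median of 0.15. B2m and H2-D1 were at -0.35 (SE 0.31) and -0.14 (SE 0.48).

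Neutrophil and granulocyte precursor markers were below 0 for 11 of 11 members, median -0.34 (camera adjusted p 0.00639, and adjusted p 0.547 with an estimated correlation). The DMSO library of mouse b stood apart in this list, with a median deviation of 1.10 against -0.08 and -0.16 in the other DMSO libraries. Without it the adjusted p was 0.713, and without the thiothixene library of mouse a 0.13. S100a8 measured 86.3 ± 10.5 against 141 ± 82.2 CPM and S100a9 had a log2 fold change of -0.66 (SE 0.39). The same library was highest in macrophage identity genes, at 0.77, a list with 11 of 14 members below 0 (median -0.26, camera adjusted p 0.113, and 0.0198 without the DMSO library of mouse c, with 0.687 at an estimated correlation over all libraries). Lyz2 was at -0.40 (SE 0.35) and Mpeg1 at 0.43 (SE 0.26).

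**Figure D3:**
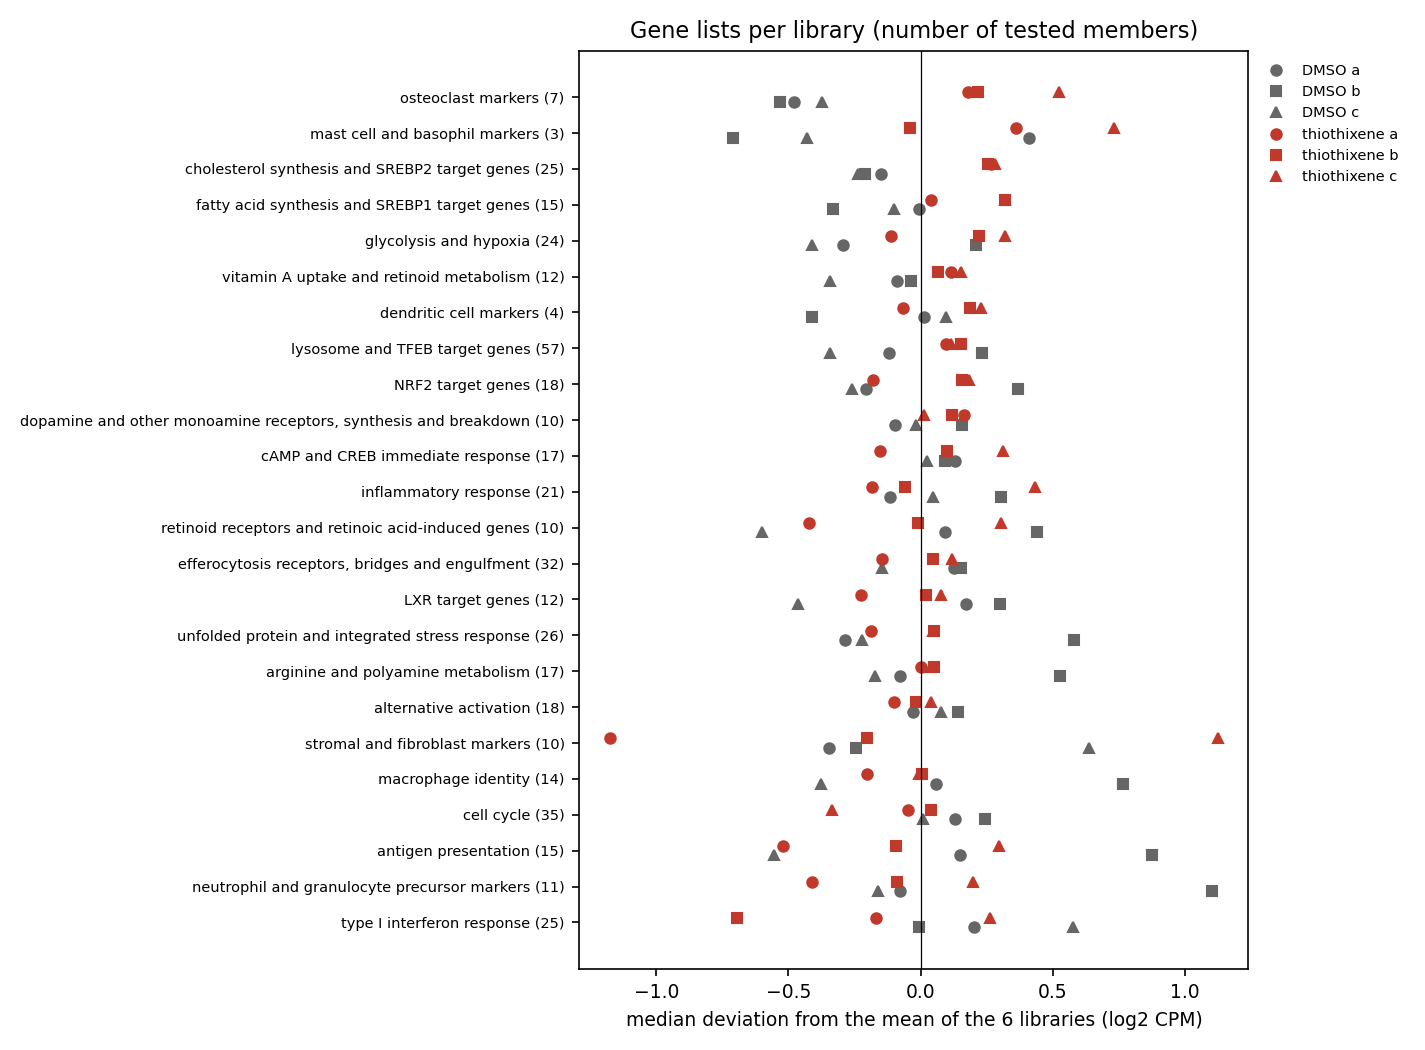
Median deviation of each gene list's tested members from the mean of the 6 libraries, in log2 CPM, per library, with DMSO in grey, thiothixene in red and symbols for mice a, b and c. The vitamin A, cholesterol, fatty acid and osteoclast lists were higher in all 3 thiothixene libraries than in all 3 DMSO libraries. These were 4 of 24 lists (16.7%), where chance gives 10% if the pairing by mouse is ignored.

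The lists closest to the study's title did not pass camera. Vitamin A uptake and retinoid metabolism had 7 of 12 members above 0 and a median of 0.24 (adjusted p 0.0617, and 0.471 with an estimated correlation of -0.056). Without the DMSO library of mouse b its adjusted p was 0.0172, and with offsets for GC content and length, chosen after the data were seen, 0.0179 (0.383 with an estimated correlation). The abundant members Fabp5 and Dhrs3 were at 0.31 (SE 0.60) and -0.22 (SE 0.39). Retinoid receptors and retinoic acid-induced genes had 4 of 10 above 0 (adjusted p 0.613). Efferocytosis receptors, bridges and engulfment genes had 12 of 32 above 0, a median of -0.04 and a mean of 0.00 (adjusted p 0.656). Lrp1 was at 0.32 (SE 0.37) and Cd36 at 0.38 (SE 0.36). Adjusted over the list alone 0 efferocytosis members passed. With offsets for GC content and length 1 did, P2ry2 at 1.30 (SE 0.25), named after its value was seen. Arginine and polyamine genes had 6 of 17 above 0, with a median of -0.11 and a mean of 0.02 (adjusted p 0.63), Slc3a2 at -0.36 (SE 0.42) and Azin1 at 0.58 (SE 0.43). Alternative activation genes had 7 of 18 above 0, median -0.06 and mean 0.00 (adjusted p 0.613), with Mrc1 at -0.17 (SE 0.41) and Tgm2 at -0.12 (SE 0.38). Members of this list, chosen after their values were seen, lay on both sides of 0, with Egr2 at 2.01 (SE 0.60), Clec7a at 0.90 (SE 0.28) and Cd163 at -1.45 (SE 0.48). Adjusted over the list alone 0 members passed, and 4 did with offsets for GC content and length, these 3 and Il4ra at -0.68 (SE 0.17). Dopamine and other monoamine genes had 5 of 10 above 0, median 0.17 (adjusted p 0.613). The adrenergic receptor gene Adra1a measured 78.9 ± 16.5 against 42.0 ± 8.62 CPM without passing the test. Genes of the cAMP and CREB response had 9 of 17 above 0, with a median of -0.02 and a mean of 0.05 (adjusted p 0.95), Thbs1 at 0.11 (SE 0.54) and Rgs2 at -0.16 (SE 0.30).

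Mitochondrially encoded genes took 1.37 ± 0.238% of gene counts with thiothixene and 1.43 ± 0.527% with DMSO (SD, n = 3, two-sided exact permutation p = 1). The permutation ignored the pairing by mouse, and 3 against 3 unpaired libraries cannot give a p of less than 0.1. The difference was smaller than the spread between replicates.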

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

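The GC and length offsets, the library quality weights, DESeq2 with the block and the fits without libraries that stand apart were chosen after the data were seen. With GC and length offsets, with and without the replicate block, edgeR called 0 genes. The count of 0 called genes also held in edgeR with the replicate block, RLE size factors and the stricter filter and in limma-voom. It was 1 (higher) without a low-count filter, 2 (both higher) in DESeq2, 1 (higher) in DESeq2 with the replicate block, 25 (9 higher, 16 lower) with library quality weights and 1105 (636 higher, 469 lower) without the 3 libraries that stand apart. Leaving out single libraries or mice gave 0 to 45 calls, 0 to 11 higher and 0 to 34 lower, and the 45 came without mouse c with the block kept. The cause was not tested, except that fewer libraries entered those fits. Arg1 stayed below 0 and uncalled in every setting that kept it, and the stricter filter removed it. Stra6l kept its direction, with log2 fold changes from 2.15 to 2.57. Of 24 lists, 9 passed with the preset correlation, 0 with an estimated correlation and 1 with fry, while after the offsets 11 passed with the preset and 0 with an estimated correlation, and leaving out single libraries gave 4 to 9, the 4 without the DMSO library of mouse a. Without the 3 libraries that stand apart 8 lists passed. The neutrophil and antigen presentation lists (adjusted p 0.892 for both), interferon (0.052) and osteoclast lists (0.073) lost the call. The unfolded protein and NRF2 lists (2.37e-06 for both) and the stromal list (0.0238) gained it, and the cholesterol, fatty acid, lysosome, glycolysis and cell cycle lists passed in both fits. A lone DMSO library stands in that fit, and in the fit without the DMSO libraries of mice b and c, so their p-values rest on the spread of the thiothixene libraries. The replicate block ended the call of the antigen presentation list and of Atp6v0d2 within its list and changed no other list or gene call in camera or edgeR. Counts were lowest for Arg1 and the dopamine receptor genes, and the DMSO library of mouse b, with 10472349 counts, is the thinnest.

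Among named genes and lists, 230 comparisons across settings changed sign, 1691 kept direction and side of the threshold, 68 gained a call and 50 lost one. The values that follow are log2 fold changes, or medians for lists, of results that were not called in edgeR or camera with all 6 libraries, the antigen presentation list excepted. For lists the direction is that of the test, whose sign the median need not share. The cause was not tested. With library quality weights the sign turned for Dhrs3 0.17, Slc3a2 0.060, Apoe 0.16, Lpl 0.084, Bst2 0.092, H2-D1 0.11, Pcna 0.19, Hspa5 0.10, Hsp90b1 0.064, Fth1 0.47, Ftl1 0.48 and Pkm 0.30. That setting also turned Gapdh 0.23, Cd79b 0.24 and Nfatc1 -0.13. Without the DMSO libraries of mice b and c the sign turned for Dhrs3 0.17, Rgs2 0.21, Slc3a2 0.013, Lrp1 -0.22, Lpl 0.28, Bst2 0.046, B2m 0.13, Pcna 0.32, Hspa5 0.28, Hsp90b1 0.31, Fth1 0.49 and Ftl1 0.18. That setting also turned Pkm 0.25, Gapdh 0.099, S100a8 0.035, Itgae 0.069, Cd79b 0.13, Alas2 0.14, Nfatc1 -0.26, the list of arginine and polyamine metabolism 0.065, the list of inflammatory response 0.064, the list of dendritic cell markers -0.24, the list of stromal and fibroblast markers 0.33 and the list of mast cell and basophil markers -0.11. Without the 3 libraries that stand apart the sign turned for Dhrs3 0.21, Tgm2 0.022, Slc3a2 0.17, Lrp1 -0.12, Apoe 0.24, Lpl 0.23, Bst2 0.32, H2-D1 0.13, Pcna 0.28, Hspa5 0.20, Hsp90b1 0.13 and Fth1 0.58. That setting also turned Ftl1 0.52, Pkm 0.42, Gapdh 0.29, S100a8 0.073, Cd79b 0.41, Nfatc1 -0.28, the list of cAMP and CREB immediate response -0.011, the list of arginine and polyamine metabolism 0.17, the list of inflammatory response 0.23, the list of dendritic cell markers 0.11, the list of stromal and fibroblast markers 0.87 and the list of mast cell and basophil markers 0.10. In that fit, with its lone DMSO library, Fth1 (adjusted p 0.000361), Ftl1 (0.00119), Pkm (0.00736) and the stromal list passed in the turned direction. With GC and length offsets the sign turned for Lrp1 -0.026, Ctsb -0.062, Fdft1 -0.062, H2-D1 0.005, Col1a1 -0.41, Col1a2 -0.19 and the list of inflammatory response -0.14. With RLE size factors the sign turned for Fdft1 -0.015. With the stricter filter the sign turned for Fdft1 -0.004. In DESeq2 the sign turned for Fdft1 -0.008. With the offsets and the replicate block the sign turned for Fdft1 -0.052, H2-D1 0.012, Fth1 0.073, Ftl1 0.061, Alas2 0.21, Col1a1 -0.50, Col1a2 -0.16 and Cpa3 0.14. In limma-voom the sign turned for H2-D1 0.032, Fth1 0.051, Ftl1 0.17 and Col1a1 -0.22. With the replicate block the sign turned for Fth1 0.042, Ftl1 0.022, Alas2 0.14, Col1a1 -0.24 and Cpa3 0.093. In DESeq2 with the replicate block the sign turned for Fth1 0.035, Ftl1 0.016, Alas2 0.14, Col1a1 -0.25 and Cpa3 0.15. Without a low-count filter the sign turned for Itgae 0.012, the list of dopamine and other monoamine receptors, synthesis and breakdown -0.17 and the list of cAMP and CREB immediate response 0.007. In fry the direction turned for the lists of cAMP and CREB immediate response, of efferocytosis receptors, bridges and engulfment and of alternative activation. Fry gives no median of its own, and the medians over all 6 libraries stayed at -0.024, -0.044 and -0.056. With the offsets and an estimated correlation the sign turned for the list of inflammatory response -0.14. Over the fits that leave out a single library or both libraries of a mouse, values crossed 0 for Fabp5 -0.13 to 1.28, Dhrs3 -0.47 to 0.29, Tgm2 -0.53 to 0.22, Thbs1 -0.28 to 0.90, Rgs2 -0.51 to 0.069. Ranges were also Slc3a2 -0.77 to 0.17, Lrp1 -0.010 to 0.88, Ctsb -0.028 to 0.45, Fdft1 -0.30 to 0.27, Apoe -1.37 to 0.59, Lpl -0.30 to 0.088. Ranges were also Mrc1 -0.50 to 0.35, Bst2 -1.36 to 0.48, H2-D1 -0.65 to 0.39, Pcna -0.25 to 0.13, Mki67 -0.42 to 0.45, Hspa5 -0.41 to 0.048. Ranges were also Hsp90b1 -0.46 to 0.29, Fth1 -0.41 to 0.52, Ftl1 -1.003 to 0.82, Pkm -0.52 to 0.37, Gapdh -0.80 to 0.44, Itgae -0.12 to 0.049. Ranges were also Alas2 -0.65 to 1.05, Col1a1 -0.86 to 0.60, Col1a2 -0.56 to 0.60, Cpa3 -0.62 to 0.57, the list of retinoid receptors and retinoic acid-induced genes -0.38 to 0.18, the list of dopamine and other monoamine receptors, synthesis and breakdown -0.20 to 0.32. Ranges were also the list of cAMP and CREB immediate response -0.086 to 0.22, the list of arginine and polyamine metabolism -0.17 to 0.16, the list of efferocytosis receptors, bridges and engulfment -0.10 to 0.10, the list of LXR target genes -0.30 to 0.20, the list of inflammatory response -0.28 to 0.19, the list of antigen presentation -0.54 to 0.15. Ranges were also the list of unfolded protein and integrated stress response -0.074 to 0.35, the list of dendritic cell markers -0.37 to 0.35, the list of stromal and fibroblast markers -0.82 to 0.44.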

Other observations

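The list tests in this part were fixed before the data were examined, and the tests of the spread, of other splits, of Stra6l and of antisense counts were chosen after the result, or values related to it, had been seen. Further gene groups were measured. NRF2 target genes had 12 of 18 members above 0, median 0.14 (camera adjusted p 0.0622, and 0.000354 without the DMSO library of mouse b or 0.0279 without the thiothixene library of mouse a). With offsets for GC content and length it was 0.0113. With an estimated correlation the adjusted p was 0.659, and 0.456 after the offsets. The ferritin genes Fth1 and Ftl1 were at -0.12 (SE 0.42) and -0.29 (SE 0.76). Inflammatory response genes had 9 of 21 above 0, with a median of -0.15 and a mean of 0.03 (adjusted p 0.622). Ccl2 measured 177 ± 80.9 against 97.5 ± 69.4 CPM and Ccl3 69.5 ± 12.2 against 47.9 ± 20.4 CPM (SD, n = 3). Unfolded protein and stress response genes had 13 of 26 above 0 (adjusted p 0.613, and 0.00158 without the DMSO library of mouse b, with 0.776 at an estimated correlation over all libraries), with Hspa5 at -0.17 (SE 0.29) and Hsp90b1 at -0.13 (SE 0.33).

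Markers of other cell types were also measured. Dendritic cell markers had 2 of 4 above 0 (adjusted p 0.613), with Itgax at 20.4 ± 7.18 against 9.53 ± 3.99 CPM, higher in all 3 thiothixene libraries than in all 3 DMSO libraries, and Itgae at 18.2 ± 1.72 against 18.5 ± 1.05 CPM. Stromal markers had 5 of 10 above 0 and a median of -0.22 (adjusted p 0.553, and 0.776 with an estimated correlation). Without the thiothixene library of mouse c the median was -0.82 (adjusted p 0.000579), and without the 3 libraries that stand apart it was 0.87 (0.0238), so the direction depended on which libraries entered. Col1a1 was at 79.1 ± 69.1 against 71.3 ± 19.0 CPM and Col1a2 at 63.6 ± 48.3 against 53.5 ± 19.7 CPM. Mast cell markers had 2 of 3 above 0 (adjusted p 0.252), with Kit at 2.04 and 1.20 CPM and Cpa3 at 0.605 and 0.661 CPM. Lymphocyte markers had 2 tested members, too few for camera, Cd4 at 12.1 and 7.64 CPM, also higher in all 3 thiothixene libraries, and Cd79b at 2.69 and 4.35 CPM. The erythroid list had 1, Alas2 at 2.33 and 2.43 CPM, whose edgeR log2 fold change was -0.08 and limma coefficient 0.11.

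The spread between libraries of the same treatment is the pattern a reader may most want to follow up. The common dispersion was 0.212 over the 6 libraries and 0.0197 over the thiothixene libraries of mice b and c with the DMSO library of mouse a, picked because they lie together. Offsets for GC content and length left 0.128, leaving out the thin DMSO library of mouse b left 0.152, and genes of mean CPM at least 100 had 0.131 where those 3 libraries had 0.00615. With all libraries thinned to the shallowest it was 0.183. Random thinning of counts leaves such a dispersion largely as it is whatever its cause, so that value does not bear on depth. Without the DMSO library of mouse b most of the dispersion was still there, which argues against that library's depth as the whole cause. Because the 3 libraries were picked for lying together, the values do not decide on a GC and length trend or few starting molecules, and both stay open. The DMSO library of mouse c had 16477 genes detected and 393 genes at 1 count, against 19649 and 1429 in that of mouse a. The DMSO library of mouse b, which also stands apart, had 1939 genes at 1 count, the most of the 6 libraries. Differences between mice and in RNA handling were not tested.

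The real split of the 6 libraries called 0 genes and the highest other also 0. Since any split gives at least 0, the 10 of 10 splits that gave as many test nothing. At an unadjusted p under 0.05 the real split gave 256 genes, 5 of 10 splits gave as many, and the highest other gave 2283. That highest split set the thiothixene library of mouse a with the DMSO libraries of mice a and c, and points to a structure of the samples other than treatment. Of these, thiothixene a and DMSO c had 4.978% and 4.516% of reads not aligned. Their deviations correlated with GC content at -0.523 and -0.618. The remaining libraries, DMSO a included, had 1.85% to 2.31% of reads not aligned and correlations from 0.176 to 0.455. The cause was not tested. The real split shifted 9 lists, 1 of 10 splits (the real one) did so, and the highest other shifted 6. Of the 10, 4 put the libraries of each mouse on opposite sides, as the real one does, while the rest keep both libraries of a mouse together for some mice. Among the others of these 4, the most genes were 948, in a split that shifted 3 lists. The most lists were 4, in a different split that gave 40 genes. With 10 splits a share under 0.05 cannot be reached.

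Stra6l led the ranking although the libraries spread widely. Were its rank due to the GC and length trend, the difference would shrink toward 0 with the offsets. It was 2.19 (SE 0.22) after them and 2.35 (SE 0.33) before, which argues against that trend as the whole cause. A drug response of Stra6l may be the reason, as a hypothesis. The rule fixed before the data were examined named Stra6l, while the offsets were chosen after values had been seen. The design of 3 against 3 libraries keeps chance open.

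Between 46.0% and 47.2% of uniquely placed reads fell outside genes. A candidate explanation is that reads not marked by strand were counted by strand. In 16 pairs of an antisense gene lying inside the exons of an abundant gene, the antisense gene had a median of 1.156 times the host's counts per exon base, with 11 pairs at 0.5 or more and 5 under 0.05. Among the 11, ratios ran from 5.45 to 8.84 for the antisense genes in Coro1c, Sdc3, Maf, Gnas and Tgoln1, far above equal counts per base. The median is what that explanation needs, and neither these high pairs nor the 5 low pairs are. Since the median lies between pairs that depart on both sides, it does not decide, and the explanation stays open. If it holds, levels of antisense genes may include reads of their hosts. No biological explanation was tested.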
